A study of Mus musculus with 18 samples.

How the data were processed

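RNA was extracted from mouse liver with a phenol-based reagent and made into sequencing libraries with a commercial kit, per the labels' protocols. The labels describe 18 samples in 6 groups of 3, formed by 3 genotypes and 2 kinds of surgery. The submitters' processing notes name Trimmomatic 0.33, STAR 2.5.0a and DESeq2 1.14 with the mouse build GRCm38. The read counter, the annotation and any filter are not given in the sources used here. By its name, the single table analysed here holds gene counts that the authors divided by DESeq2 size factors.

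The 18 value columns of that table were not used. Their headers consist of IR or W followed by a number, with 9 columns of each kind. The sample titles give a genotype, a surgery and a number from 1 to 3. No header therefore matches one sample and no other, and no header gives a genotype. The meaning of W is stated neither in the labels nor in the header. By elimination it would stand for sham surgery, since the 9 IR columns equal the 9 ischemia-reperfusion samples in number, 9 sham samples remain and only 6 samples are wild type. This reading rests on every column being a sample of this series, and gives a surgery but no genotype. It was not used, because the groups had been fixed as combinations of genotype and surgery and no planned comparison pooled the genotypes. For surgery this is a limit of the plan, not of the headers. Columns were not assigned by their order or by the expression of the targeted genes, because either would have been a guess at the genotype.

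Only the gene identifiers and the header line entered the results reported here, read with Python 3.11.15. Identifiers were matched without their version suffix to the symbols of GENCODE vM21, which is also built on GRCm38. Coordinates are 1-based and come from the GENCODE vM21 primary assembly annotation. Gene lists were fixed before the data were examined, and their members were looked up by symbol. The 10 comparisons planned between groups, their alternatives and the gene list tests were not carried out. Depth per sample is not reported, because no column was assigned to a sample. By the name of the table, its counts had also already been divided by size factors.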

Results

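Liver RNA was profiled from wild-type mice and from mice lacking Il22 or Il22bp after ischemia-reperfusion or sham surgery. Ischemia-reperfusion interrupts and then restores the blood supply of the liver. IL-22 is a cytokine that acts on epithelial cells and hepatocytes, and IL-22BP is its soluble binding protein, encoded by Il22ra2. The 3 genotypes and 2 surgeries formed 6 groups of 3 samples, so that 9 samples had undergone ischemia-reperfusion and 9 had undergone sham surgery. The design asks how the hepatic response to ischemia-reperfusion depends on IL-22 and on its binding protein.

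No expression difference between genotypes or surgeries is reported. The table has 9 columns headed IR and 9 headed W, each followed by a number, and none carries a genotype. Whether either knockout altered expression, with or without ischemia-reperfusion, was therefore not analysed here, and the knockouts were not checked in the targeted genes. The surgery is a different case. The 9 IR headers equal in number the 9 ischemia-reperfusion samples, which leaves the 9 W headers for the 9 sham samples if every column belongs to this series. Reading the headers this way would permit a comparison of 9 against 9 libraries with genotypes mixed. That comparison was not made here, because it was not among those planned. The groups fixed before the data were examined combine genotype with surgery, and no column could be given such a group. The effect of surgery was thus left unexamined by choice of plan.

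Both targeted genes were among the features of the table. Il22 (ENSMUSG00000074695) is a protein-coding gene on the plus strand of chromosome 10, from 118204942 to 118210047 in GRCm38. Il22ra2 (ENSMUSG00000039760) is a protein-coding gene on the plus strand of the same chromosome, from 19621998 to 19634681. Iltifb (ENSMUSG00000090461), a close paralogue of Il22, was listed as a separate feature on the minus strand of chromosome 10, from 118289629 to 118295038. Reads from Il22 and Iltifb could be split between the 2 features, depending on how the authors counted reads that align to both. The receptor subunits Il22ra1 (ENSMUSG00000037157), on chromosome 4 from 135728172 to 135752140, and Il10rb (ENSMUSG00000022969), on chromosome 16 from 91406164 to 91425834, were also listed.

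The table listed 47729 distinct gene identifiers. Of these, 47224 (98.9%) were paired with a symbol in the GENCODE vM21 symbol table and 505 were not. Gene types came from the GENCODE vM21 primary assembly annotation, in which 47310 of the identifiers were found. Protein-coding genes made up 21697 identifiers, or 45.5% of all identifiers in the table, including those without a gene type. Processed pseudogenes accounted for 6667 identifiers (14.0%) and long intergenic noncoding RNAs for 3543 (7.42%). Of the 604 distinct genes in 38 lists fixed in advance, 601 were found by symbol, and 36 lists were found in full. These lists included 24 acute phase and STAT3 target genes, 37 chemokines and inflammatory cytokines, 32 interferon-stimulated genes, 16 neutrophil markers and 13 hepatocyte markers. The exceptions were Ctgf and Cyr61, in the list for matrix and wound repair, and Ahsp, in the erythroid list. They were looked up by these symbols only, so the genes may still be listed under another symbol. Presence in the table says only that a gene was a counted feature, not that it was expressed.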

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

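The symbol table paired 47224 identifiers with a symbol, and 47310 identifiers were found in the GENCODE vM21 primary assembly annotation. Of the paired identifiers, 34659 had a symbol that the RefSeq gene table also holds. These counts measure different things, so they do not test how robust the pairing is. The counts from the annotation and from RefSeq were chosen after seeing the data. The alternatives planned for the 10 comparisons (pseudocount, filter, scaling, libraries in the fit, replicate block, edgeR, DESeq2 and leaving out each replicate), for the gene lists, for the similarity of responses and for the position of knockout calls were not run, because no library could be assigned to a genotype and so to one of the 6 groups of genotype and surgery. No paired analysis was possible because the columns carry no number that identifies a sample of one group. This holds for the 6 groups of genotype and surgery. Whether IR and W columns with the same number belong together was not examined. The labels also do not say that equal numbers in the titles link samples of different groups. The titles alone would therefore not have justified pairing.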
